A study of Mus musculus with 6 samples.

How the data were processed

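Foxp3-positive CD4 T cells of mesenteric lymph nodes were measured on 6 one-colour Affymetrix mouse arrays, 3 of iTreg from TBmc mice fed ovalbumin and 3 of total Treg from WT mice; groups and replicate numbers were taken from the sample titles. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The deposited values are MAS5 intensity signals on a linear scale, one per probe set, per the submitters' processing notes, and the version of MAS5 is not given in the sources used here. Every deposited value was above 0, and each array had a 2% trimmed mean of 150.0, so the arrays had been scaled to one level before deposit. Detection calls were not used here. The labels do not say whether replicates came from separate mice, and p-values then measure the spread between these arrays, which may be technical in part. The number of arrays limits the precision. In a sort by Foxp3 reporter and, for iTreg, by absence of Nrp, genes used for the gate are no independent finding.

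The table held 45101 probe sets, 64 of them controls. The platform annotation table gave 34945 probe sets 1 gene symbol, 932 several and 9160 none; those with several or none, some well-known T cell genes among them, were not analysed here. Symbols were checked against RefSeq names of the GRCm38.p6 annotation, and 204 probe sets kept an older symbol. The files name no genome build and no coordinates are given. Signals were transformed as log2(signal + 16), so that log2 differences understate the change of genes with low signals. Of the probe sets of a gene the one with the highest mean over all 6 arrays was used, which left 18193 genes; those with a mean at or above the 40th percentile, 4.99 on the log2 scale, were tested, 10916 in all. Of 73 named genes, 32 had more than 1 probe set above that level, and in 6 of them these differed in sign: Capg, Cdc20, Dntt, Hmgcs1, Igfbp4 and Trav9d-3. In 19 of the 32, these 6 included, some other probe set above that level gave an opposite difference or one more than 2-fold smaller on the log2 scale than the probe set used. As a measure of background, 27 bacterial control probe sets without a spiked target reached a signal of at most 28.5.

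The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) with Benjamini-Hochberg adjustment at 0.05, two-sided, as iTreg minus WT Treg. Gene lists were tested with camera at a preset correlation of 0.01 where at least 3 members were measured, adjusted over the lists, and again with camera's estimated correlation and with fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. The design, the 35 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Named were the 10 largest differences in each direction among genes past the threshold whose groups did not overlap, filled up with the largest at an unadjusted p under 0.01 and without overlap, predicted genes left out; Nrp1, Ikzf2, Swap70, Foxp3, Dapl1 and Igfbp4; and up to 4 members of each list with the smallest p (4 for lists that passed and for the T cell receptor list, 1 for the others). Genes of the receptor and sex-linked lists were ranked only within their list. Array quality measures were compared with exact permutation tests.

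On simulated data made from these arrays' means and spreads for the comparison of iTreg with WT Treg, with 10916 genes and 200 of them changed, limma recovered 14.0% of genes changed by 1 log2 unit, 88.9% of those changed by 2 and 99.9% of those changed by 3, and 6.19% of calls were false. The simulation has independent genes, so its camera results, 100% of shifted and 0% of unshifted lists called, say nothing about correlated lists. Its recovery rates rest on the 200 planted changes, on independent genes and on smoothed variances. They do not give the share that the real comparison would find. On the real arrays 3 genes were called, and Pde3b (2.94), Plagl1 (-2.87) and Cd83 (-2.70) did not pass. Alternatives were pseudocounts of 1 and 64, quantile normalization, median scaling, no filter and a 60th percentile filter, the variance model without a trend or with robust estimation, array weights, every probe set, the mean of probe sets, probe sets specific by name, Welch's test, the replicate number as a block, each array left out, and both arrays with label doubts left out. Specific by name means a name without the ending _a_at, _s_at or _x_at. A probe set left out by this rule is not thereby shown to be unspecific. Leaving Nrp1 out of the thymic Treg marker list was added after seeing the data. Leaving out the replicate 3 array of each group was added after seeing that their spike-in controls were brighter after scaling, that is, that these arrays were dimmer before it.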

Results

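Regulatory T cells (Treg), CD4 T cells that express the transcription factor Foxp3, were sorted from mesenteric lymph nodes of mice aged 4 to 6 weeks and profiled on Affymetrix mouse arrays. One group of 3 arrays holds induced Treg (iTreg), taken after 1 week of ovalbumin given orally at 1% to TBmc mice and gated as negative for Nrp. TBmc mice carry a single T cell receptor against ovalbumin and a single B cell receptor on a recombinase-deficient background. The other group of 3 arrays holds total Treg from wild-type (WT) BALB/c mice with a Foxp3-GFP reporter. The comparison asks how Treg induced outside the thymus differ from the total Treg pool. Median MAS5 signals per array were 26.8, 27.5 and 24.3 for iTreg replicates 1, 2 and 3 and 32.3, 31.7 and 21.1 for WT replicates 1, 2 and 3. The labels of 2 arrays disagree with their groups: WT replicate 1 has the Nrp-negative cell type label despite its title of total Treg, and the strain label of iTreg replicate 1 does not name TBmc. The genotype, receptor, feeding and gate differ together between the groups, so no difference below can be assigned to one of them.

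The genes that fell in iTreg were Nt5e, Flicr and the receptor segment Trav12n-1. Nt5e, the CD73 ecto-enzyme that makes adenosine from AMP, had a mean signal of 132 ± 70.0 (SD) in iTreg and 939 ± 94.5 in WT Treg, a log2 difference of -2.79 with a standard error of 0.36 (limma adjusted p = 0.0235). Flicr, a noncoding RNA encoded beside Foxp3, had 48.4 ± 2.94 against 480 ± 167, a log2 difference of -2.89 with a standard error of 0.38 (limma adjusted p = 0.0235). Trav12n-1, a T cell receptor alpha variable segment, had 6.19 ± 4.04 against 124 ± 6.59, a log2 difference of -2.67 (limma adjusted p = 0.0235). Its iTreg mean lay within the range of unspiked control probe sets, which reached a signal of 28.5. The size of its difference therefore depends on the pseudocount, from -4.35 to -1.42 over the alternatives. Each lay lower in all 3 iTreg arrays than in every WT array. The receptor differs between the groups by design, so the difference of a receptor segment cannot be read as one of Treg origin.

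Of 10916 genes tested, limma called these 3, all lower by at least 2-fold, and 0 higher. At an unadjusted p under 0.05 it gave 328 genes higher and 500 lower, 828 in all, where 546 would be expected by chance if genes were independent. Other splits of the 6 arrays gave up to 773. Welch's test called 0 genes and gave 472 at that unadjusted threshold. With each array scaled to a common median, 1 gene, Pde3b, was called higher (adjusted p = 0.0225) and 5 lower. Nt5e was still called without iTreg replicate 2 (adjusted p = 0.0119), and leaving out any other array ended that call. Leaving out any single array ended the calls of Flicr and Trav12n-1, with adjusted p from 0.0729 to 0.216. The mean of probe sets also ended the call of Nt5e (-1.86, adjusted p = 0.0986), whose other probe sets differed by -2.64 and -0.13. Without WT replicate 1, the single call was Hopx, a homeodomain gene named here after its value was seen: its signal was 912, 624 and 471 in iTreg and 955 in WT replicate 1, against 36.9 and 22.8 in WT replicates 2 and 3.

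**Figure D1:**
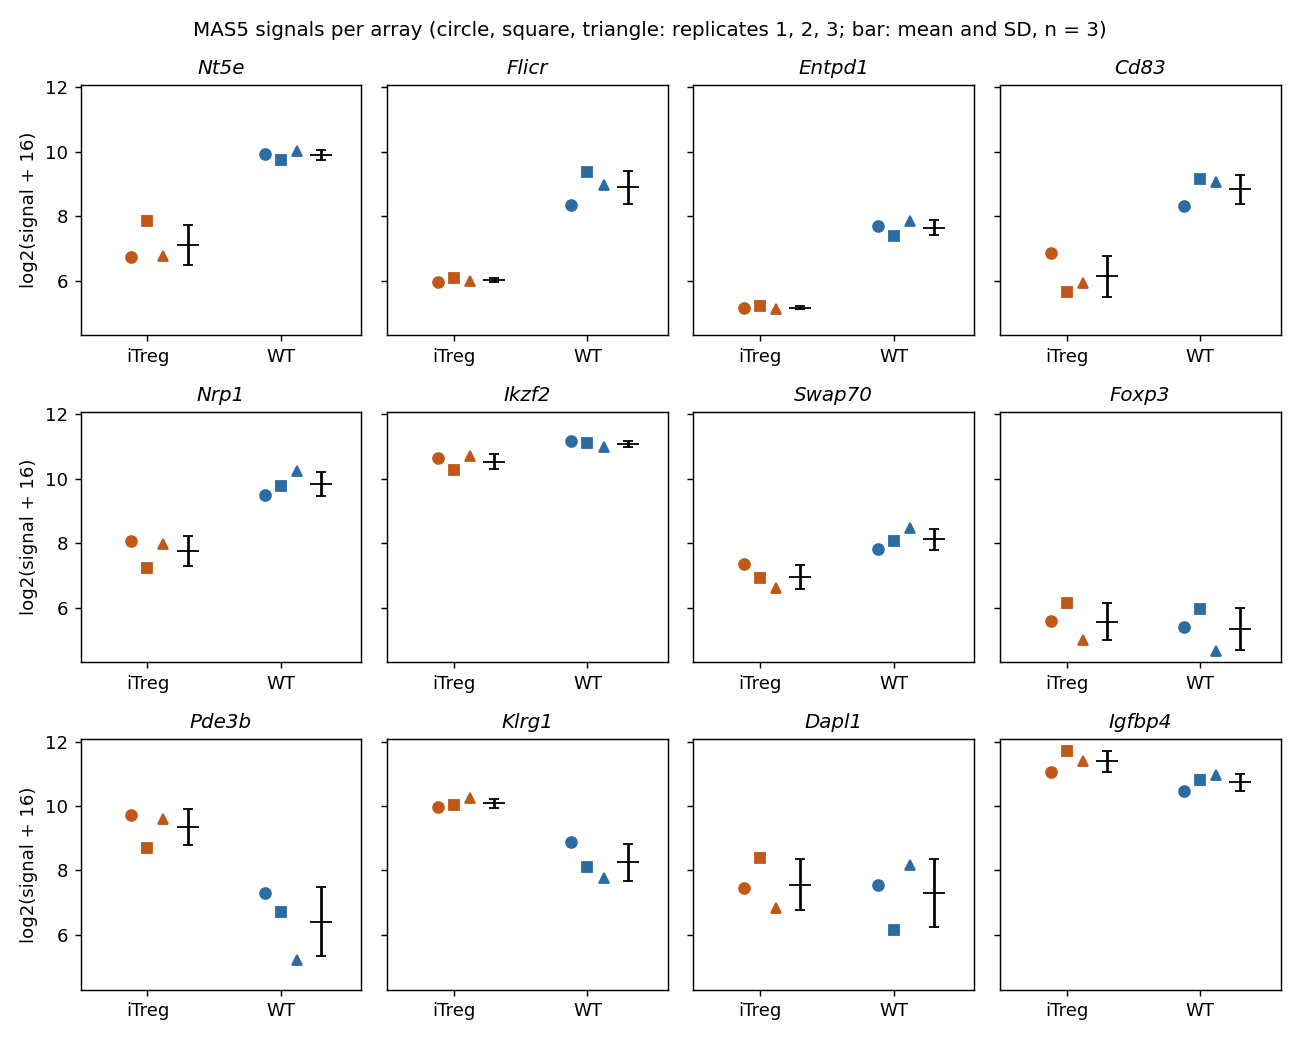
Signals of 12 genes on each of the 6 arrays, as log2(signal + 16) on the vertical axis, with iTreg in orange and WT Treg in blue; circles, squares and triangles are replicates 1, 2 and 3, and the black bar is the mean with its SD over the 3 arrays. Nt5e, Flicr, Entpd1, Cd83 and Nrp1 lie lower in all iTreg arrays than in all WT arrays, Pde3b and Klrg1 lie higher, and Foxp3 and Dapl1 overlap.

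The other large negative differences with groups that did not overlap and an unadjusted p under 0.01 did not pass the threshold. Plagl1, a zinc finger transcription factor, differed by -2.87 (adjusted p = 0.0996) on a probe set that can match other transcripts, with -1.09 and -0.46 on its others, and Cd83, a surface protein of activated lymphocytes, by -2.70 (adjusted p = 0.0758). The inhibitory receptor Lag3 differed by -2.54, the ATP-degrading ectonucleotidase Entpd1 (CD39) by -2.49, Scamp1 by -2.44, the proton pump subunit Atp6v0d2 by -2.41, Scg5 by -2.27 and the prion protein gene Prnp by -2.19. The other probe set of Prnp differed by -0.19. Scg5 differed by -1.38 without both replicate 3 arrays and by -3.20 to -1.76 without single arrays. Its groups barely parted: on the log2 scale WT replicate 1 was at 5.961 and iTreg replicate 1 at 5.957. WT replicates 2 and 3 were at 8.64 and 8.84. Entpd1 came closest to the threshold (adjusted p = 0.0562), and its other probe sets differed by -0.47 and -0.17. The iTreg means of Lag3, Entpd1, Scamp1, Atp6v0d2 and Prnp lay within the range of unspiked control probe sets, so the size of their differences depends on the pseudocount.

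Among genes with groups that did not overlap and an unadjusted p under 0.01, the largest positive difference was that of Pde3b, a phosphodiesterase that degrades cAMP, at 2.94 with a standard error of 0.51 (adjusted p = 0.0951). It was followed by Pde5a, which degrades cGMP, at 2.22, the ceramide synthase gene Cers6 at 2.09, Ms4a4c at 2.0, Ctla2a at 1.97, the kinetochore gene Spc24 at 1.87, Sema4a at 1.86, the inhibitory receptor Klrg1 at 1.83, Wnt5b at 1.83 and the calcium channel subunit Cacna2d2 at 1.81. Klrg1 had a mean signal of 1075 ± 106 (SD) in iTreg and 306 ± 134 in WT Treg (limma adjusted p = 0.0996). None of these genes passed in the main test; Pde3b passed with median scaling (adjusted p = 0.0225) and with array weights (2.65, adjusted p = 0.0471). Other probe sets of Pde5a differed by 1.49 and 0.91. Those of Cacna2d2 differed by 0.55 and, on a probe set below the expression filter, by -0.36. In all, 69 genes had higher and 137 lower values without overlap at an unadjusted p under 0.01; 12.9% of the tested genes had groups without overlap, where chance gives 10%.

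Genes of the Treg core were lower as a group in iTreg. The 20 measured members had a mean log2 difference of -0.92, with 16 negative and 4 positive (camera adjusted p = 1.48e-10; adjusted p = 0.295 with an estimated correlation; fry adjusted p = 0.0484). Over all genes tested 1 member fell, 0 rose and 19 did not pass; adjusted over the list alone 9 fell. The strongest were Nt5e, Entpd1, Socs2 (-2.01), a cytokine signalling suppressor, and Capg (-1.81), an actin-capping protein whose probe sets differed in sign. The other 5 probe sets of Socs2 differed by -1.64, -1.21, -0.33, -0.19 and -0.13, and their mean with the one used by -0.92. The members were unequal, with an SD of 0.92 between them. Foxp3 itself differed by 0.23 with a standard error of 0.43, from a single probe set whose mean signals were 34.0 ± 19.6 in iTreg and 27.02 ± 18.3 in WT Treg, near the upper end of the unspiked controls. The list was called without each single array, with mean differences from -1.03 to -0.82. The log2 ratio of Gapdh 3′ to 5′ signals, a measure of RNA quality, was also higher on average in iTreg. It was 3.01, 2.46 and 3.35 in iTreg replicates 1, 2 and 3 and 2.26, 2.49 and 2.33 in WT Treg. The list's mean per array was 8.40, 8.42 and 8.75 in iTreg and 9.30, 9.37 and 9.64 in WT Treg.

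The list of thymic Treg markers holds 3 genes, and 1 of them is Nrp1, on which the iTreg were gated. Its mean of -1.27 (camera adjusted p = 2.69e-04; adjusted p = 0.374 with an estimated correlation; fry adjusted p = 0.0484) is therefore set in part by the sort, Nrp1 giving 54.7% of the sum. The other 2, Swap70 and Ikzf2, had a mean of -0.86, from -0.99 to -0.78 without single arrays, and were too few to test as a list. Adjusted over the list alone all 3 fell, and 0 of them passed over all genes. The list was also chosen from what is known of this study's subject and is not independent evidence of its direction. Nrp1, a semaphorin and VEGF co-receptor, had a mean signal of 208 ± 65.3 (SD) in iTreg and 920 ± 246 in WT Treg, a log2 difference of -2.08 with a standard error of 0.34 (limma adjusted p = 0.0758). Its 4 probe sets were all lower in every iTreg array than in every WT array; this checks the gate and is no separate finding. Swap70 differed by -1.17 (adjusted p = 0.492) and Ikzf2, which encodes Helios, by -0.56 with a standard error of 0.25 (adjusted p = 0.656); the mean signal of Ikzf2 in iTreg was still 1481 ± 232. Of the genes listed as high in iTreg, Igfbp4 differed by 0.64 (adjusted p = 0.633), with 1 of its 6 probe sets opposite in sign, and Dapl1 by 0.27 (adjusted p = 0.934), with overlapping groups; this list of 2, with a mean of 0.46, was too short to test.

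Effector Treg genes were lower as a group, with a mean difference of -0.49 over 22 members, 16 negative and 6 positive (camera adjusted p = 0.00427; adjusted p = 0.533 with an estimated correlation). None passed over all genes, with 7 lower and 2 higher at an unadjusted p under 0.05; adjusted over the list alone 5 fell and 1 rose. The leading members pointed both ways: Klrg1 was the one that rose over the list alone, while the cytokine Il10 (-1.75), the transcription factor Maf (-1.34, and -0.50 on the probe set that differed least) and Lag3 fell. Without iTreg replicate 2 or WT replicate 3 the group call ended (adjusted p = 0.101 and 0.1004). The Th2 list, with 5 measured members, was lower by a mean of -0.74 (camera adjusted p = 0.0448; adjusted p = 0.442 with an estimated correlation), led by Il10 and the transcription factor Nfil3 (-1.50), which both fell adjusted over the list alone. Neither is specific to Th2 cells, and the Th2 regulator Gata3 differed by 0.28 and the chemokine receptor Ccr4 by -0.60, with -1.28 to -0.11 for Ccr4 without single arrays. The Th2 call ended without iTreg replicate 1 (adjusted p = 0.116), iTreg replicate 2 (adjusted p = 0.213) or WT replicate 1 (adjusted p = 0.468). Its mean was -0.39 without WT replicate 1 and -0.28 without both arrays with label doubts. Il10 belongs to the Treg core, effector Treg and Th2 lists, so these calls are not independent of each other. The mean signal of Il10 was 3.40 in iTreg, within the range of unspiked controls, and 52.0 in WT Treg.

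Naive or central T cell genes were higher as a group, with a mean difference of 0.22 over 17 members, 12 positive and 5 negative (camera adjusted p = 0.0448; adjusted p = 0.533 with an estimated correlation). None passed over all genes, and 1 rose adjusted over the list alone: Ccr9, a gut-homing chemokine receptor, at 1.47. Its other probe sets differed by 1.55, 1.36, 0.16 and 0.15, the last being the one used with specific probe sets only. The chromatin organiser Satb1 differed by 1.01, and by 0.25 on the probe set that differed least, and the lymph node homing receptor Ccr7 by 0.70, while Il7r, the IL-7 receptor, differed by -1.20 with a standard error of 0.41. The call ended without iTreg replicate 2 (adjusted p = 0.0925), iTreg replicate 3 (adjusted p = 0.134), WT replicate 1 (adjusted p = 0.202) or WT replicate 2 (adjusted p = 0.160). Its mean was 0.35 without WT replicate 3. Per array the list's mean was 10.56, 10.63 and 10.79 in iTreg and 10.32, 10.29 and 10.72 in WT Treg. WT replicate 3 thus lay above iTreg replicates 1 and 2. The members Igfbp4 (0.64) and Dapl1 (0.27) are also the genes listed as high in iTreg, so this list is not fully independent of that listing.

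Type I interferon response genes were higher as a group, with a mean difference of 0.36 over 25 members, 19 positive and 6 negative (camera adjusted p = 0.00408; adjusted p = 0.533 with an estimated correlation). Adjusted over the list alone, Ifit1 (1.49), an inhibitor of viral translation, rose, and Gbp3 (-1.37), a guanylate-binding GTPase, and Oas3 (-1.83), an oligoadenylate synthetase, fell; none passed over all genes. Ifit2 differed by 0.84. The call ended without iTreg replicate 2 (adjusted p = 0.0721). The mean was 0.59 without WT replicate 1. Per array the list's mean was 8.60, 8.66 and 8.32 in iTreg and 8.64, 7.93 and 7.93 in WT Treg. WT replicate 1, an array with a label doubt, thus lay above iTreg replicates 1 and 3. Immediate early and stress genes were higher, with a mean difference of 0.50 over 18 members, 15 positive and 3 negative (camera adjusted p = 0.0448; adjusted p = 0.684 with an estimated correlation). None passed over all genes or over the list alone, and the member with the smallest p, Ier2, went the other way at -0.99. The heat shock genes Hspa1b and Hspa1a differed by 2.47 and 1.44 and the stress-induced Ppp1r15a by 1.05, each with overlapping groups. Without single arrays they ranged from 1.58 to 3.67, 0.40 to 2.53 and 0.61 to 1.81, and the other probe sets of Hspa1b differed by 1.09 and 0.53. The list's mean per array was 9.46, 9.23 and 7.87 in iTreg and 9.16, 7.68 and 8.22 in WT Treg, so it varied within both groups; the call ended without iTreg replicate 1 (adjusted p = 0.338), iTreg replicate 2 (adjusted p = 0.190) or WT replicate 2 (adjusted p = 0.402). Its mean was 0.20 without WT replicate 2, 0.24 without iTreg replicate 1, 0.95 without WT replicate 1 and 0.99 without iTreg replicate 3.

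Unfolded protein response genes were lower as a group, with a mean difference of -0.40 over 16 members, 11 negative and 5 positive (camera adjusted p = 0.0398; adjusted p = 0.436 with an estimated correlation). None passed over all genes or over the list alone. The endoplasmic reticulum chaperones and folding factors Pdia4 (-1.09), Manf (-0.81) and Hsp90b1 (-0.70) and the pseudokinase Trib3 (-1.27) had the smallest p-values. The call ended without iTreg replicate 2 (adjusted p = 0.123), WT replicate 1 (adjusted p = 0.0596) or WT replicate 3 (adjusted p = 0.1004).

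**Figure D2:**
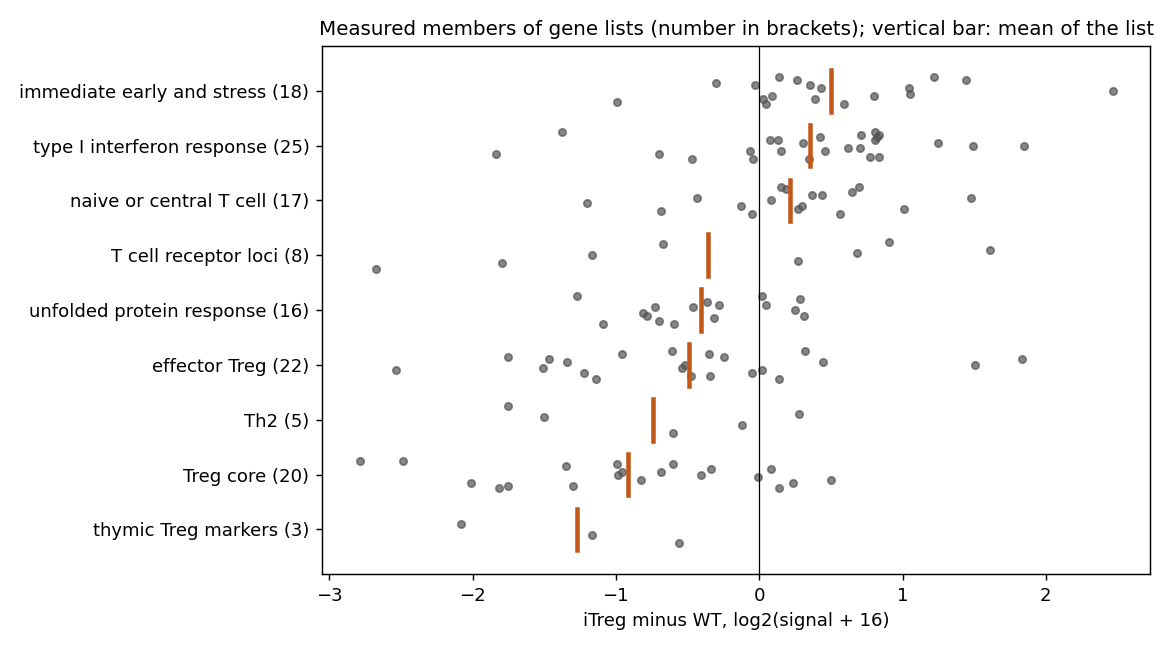
Log2 differences (iTreg minus WT Treg, log2(signal + 16), horizontal axis) of the measured members of the 8 gene lists that passed camera's test and of the T cell receptor list. Each grey point is a gene, its height within a list carries no value, and the orange bar is the list's mean, which runs from -1.27 for the thymic Treg markers to 0.50 for the immediate early and stress genes.

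Of 35 lists, 30 had at least 3 measured members and 8 passed camera's test; with an estimated correlation 0 passed (3 at an unadjusted p under 0.05), and fry called 2. Each of these counts but the 0 includes the thymic list, which the gate on Nrp1 affects. Fry called the Treg core and thymic lists, and its adjusted p ranged from 0.139 to 0.760 for the other lists that passed camera's test. Among T cell lists that did not pass, the mean difference was -0.57 for anergy (1 member, Nt5e, fell over all genes and 3 fell adjusted over the list alone), -0.29 for T cell receptor signalling, where the inhibitory receptor Cd5 differed by -1.06, and -0.30 for the IL-2 and STAT5 response, led by Socs2. Anergy passed without iTreg replicate 3 (adjusted p = 0.00567) or WT replicate 1 (adjusted p = 0.0161), T cell receptor signalling without the same arrays (adjusted p = 0.00366 and 0.0390), and the IL-2 response without iTreg replicate 3 (adjusted p = 0.00176). Without single arrays the mean ranged from -0.42 to -0.18 for T cell receptor signalling and from -0.49 to -0.19 for the IL-2 response. Adjusted over the list alone, 3 members of the IL-2 and STAT5 list fell and 1 rose. The means were -0.16 for follicular helper genes (Pdcd1, -1.22), -0.08 for Th17 genes with a median of 0.04 (Ccr6, -0.61), 0.20 for Th1 genes with a median of -0.05 (Eomes, 1.37), and 0.11 for the TGF-beta response (Tgfbr3, 0.85). Without single arrays they ranged from -0.31 to -0.064, -0.34 to 0.10, 0.046 to 0.44 and -0.13 to 0.21, so the Th17 and TGF-beta means did not keep one direction. Ccr6 ranged from -0.79 to -0.36 and Tgfbr3 from 0.54 to 1.08. Gut homing and retinoic acid genes, led by the same Ccr9 value, had a mean of -0.05 with camera's direction up, and conventional CD4 T cell genes a mean of -0.03 with a median of 0.09 (Trat1, -1.31); median scaling turned both means positive.

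Proliferation and metabolism lists did not pass. Mitosis genes had a mean difference of 0.16, led by Cdc20 at 0.94 (0.42 to 1.48 without single arrays), whose probe sets differed in sign, and passed without WT replicate 3 (adjusted p = 0.0164). DNA replication genes had -0.13 (Chaf1b, -1.19, from -1.74 to -0.73 without single arrays) and passed without iTreg replicate 3 (adjusted p = 0.0218). Glycolysis genes had -0.32, led by the enzyme gene Tpi1 at -1.09 (-1.59 to -0.68 without single arrays), and passed without iTreg replicate 3 (adjusted p = 0.00644) or WT replicate 1 (adjusted p = 0.0440). Their mean ranged from -0.41 to -0.21 without single arrays. Oxidative phosphorylation genes had -0.21 (Cycs, -1.02, with -0.94 on another probe set, but -0.24 with specific probe sets only). Ribosomal protein genes had -0.19 (Rps19, -0.89). Both lists passed without WT replicate 2 (adjusted p = 0.00136 and 3.86e-04). Without WT replicate 3 their means were -0.040 and -0.046. Cholesterol synthesis genes had -0.26, with 13 of 15 negative, although Hmgcs1, an early enzyme of the pathway, differed by 1.01 and its probe sets disagreed in sign. The cholesterol list passed with every probe set (adjusted p = 0.0107), the mean of probe sets (adjusted p = 0.0259) and specific probe sets only (adjusted p = 0.0126).

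Markers of other cells did not pass as lists in the main test. The mean difference was 0.28 for B cells (Ighm, 0.97), which passed with every probe set (adjusted p = 0.0226), 0.19 for MHC class II presentation (Cd74, the invariant chain, 1.79), 0.06 for macrophages and dendritic cells with 5 of 11 members negative (Lyz2, 0.87), 0.23 for stroma and endothelium (Vcam1, 0.65) and -0.25 for erythroid genes (Hba-a2, -1.40). CD8 and cytotoxic genes had a mean of 0.35, led by Eomes, and passed without iTreg replicate 3 (adjusted p = 0.0413), with no filter (adjusted p = 0.0491), with every probe set (adjusted p = 0.0112) and with the mean of probe sets (adjusted p = 0.0265). Without single arrays the mean ranged from 0.19 to 0.49 for CD8 and cytotoxic genes and from 0.0076 to 0.13 for macrophages and dendritic cells. It ranged from 0.097 to 0.27 for stroma and endothelium and from -0.87 to 0.22 for erythroid genes. Vcam1 passed the filter in only 2 of the fits without a single array, at 0.41 and 0.65. The short lists were not tested. Granulocytes with 2 measured members had a mean of 1.40, plasma cells with 2 members -0.54 (Xbp1, -0.72) and the sex-linked list with 1 member 0.24. The recombinase list had 1 measured member, Dntt, at 0.85 (from 0.40 to 1.10 without single arrays). Dntt encodes a terminal transferase and no recombinase, and its other probe sets differed by -0.06 and 0.02. The granulocyte protein gene S100a9 differed by 1.74, with a mean signal of 54.4 ± 22.9 (SD) in iTreg and 5.11 ± 6.96 in WT Treg, and its adjusted p was 0.172. Adjusted over the list alone the 2 granulocyte members rose. Their mean per array was 5.56, 6.65 and 5.35 in iTreg and 4.50, 4.39 and 4.46 in WT Treg.

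Array quality was compared with exact two-sided permutation tests, whose smallest possible p with 3 against 3 arrays is 0.1, so they cannot show that quality was equal or unequal. The median log2 signal was 5.40 ± 0.06 (SD) in iTreg and 5.46 ± 0.22 in WT Treg (exact permutation p = 0.6), and the share of genes under the expression filter was 39.2% and 38.7% (exact permutation p = 0.9). The log2 ratio of 3′ to 5′ control probe sets, which grows with RNA degradation, was 2.94 ± 0.45 and 2.36 ± 0.12 for Gapdh (exact permutation p = 0.2) and 0.21 ± 0.19 and 0.24 ± 0.09 for Actb (exact permutation p = 0.8). The Gapdh log2 ratio stayed higher in iTreg, by 0.37 to 0.82, without any single array. Spike-in controls averaged 12.9 on the log2 scale on both replicate 3 arrays and between 12.1 and 12.6 on the others. Across genes, which are not independent replicates, Spearman's rho between arrays was 0.879 to 0.931 within iTreg, 0.922 to 0.945 within WT Treg and 0.863 to 0.943 between groups. The highest pair between groups was iTreg replicate 1 with WT replicate 1, the 2 arrays with label doubts, at 0.943. This was above the rho of iTreg replicate 1 with iTreg replicates 2 and 3 (0.931 and 0.888). WT replicate 1 was also closer to iTreg replicate 2 (0.940) than either other iTreg array was, and closest to WT replicate 2 (0.945).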

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

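The alternative without both dimmer arrays, the thymic list without Nrp1 and the spike-in measure were chosen after seeing the data. Treg core kept its direction in all alternatives and passed in all that test lists except with an estimated correlation. The thymic Treg marker list holds Nrp1, low by the gate in every alternative, so its calls are no test; without Nrp1 its mean was -0.86 (-0.99 to -0.73 over the alternatives), from 2 genes and untested. By over 1.5 times moved 46 of 73 named genes and 27 of 30 lists in some alternative, and 14 and 21 without some single array. The count of changed genes was 3, all lower and all at least 2-fold. Pseudocount 1, no filter, Welch's test, both label-doubt arrays left out and both dimmer arrays left out each gave 0 changed, 0 lower and 0 at least 2-fold (794, 1156, 472, 560 and 636 at an unadjusted p under 0.05). Median scaling gave 6 changed, 1 higher and 5 lower, 6 at least 2-fold. Array weights gave 14 changed, 1 higher and 13 lower, 14 at least 2-fold, with all 3 genes shared. Leaving out single arrays gave 0 to 1 for each of changed, higher, lower and at least 2-fold. The number of lists passing, 8, became 5 with pseudocount 1, 13 with quantile normalization, 14 with no filter, 3 with the 60th percentile filter, 19 with every probe set, 12 with the mean of probe sets, 0 with an estimated correlation and 2 with fry, and 2 to 13 when single arrays were left out. Nrp1 (adjusted p from 0.0364 to 0.913 over the alternatives) passed with array weights (-1.98, adjusted p = 0.0403) and the mean of probe sets (-2.24, adjusted p = 0.0364); Ikzf2 never passed (-0.69 to -0.42). Calls of lists that passed ended for naive or central T cell (pseudocount 1, median scaling, 60th percentile filter, no trend, mean of probe sets, specific probe sets, label-doubt arrays out), Th2 (pseudocount 1, no filter, 60th percentile filter, label-doubt arrays out), immediate early and stress (pseudocount 1, 60th percentile filter, no trend, specific probe sets), effector Treg (60th percentile filter) and unfolded protein response (60th percentile filter, array weights, dimmer arrays out). Lists that had not passed did so for anergy (quantile, median scaling, no filter, array weights, every probe set, label-doubt or dimmer arrays out), T cell receptor signalling (no filter, every probe set, mean of probe sets, label-doubt arrays out), the IL-2 response (quantile, array weights, every probe set, specific probe sets, dimmer arrays out), glycolysis (quantile, no filter, every probe set), and oxidative phosphorylation and ribosomal proteins (quantile, no filter, every probe set, mean of probe sets). Lists too short for the main test passed with no filter (sex-linked) and with every probe set (genes listed as high in iTreg, plasma cells). The cause was not tested for any of these changes, except that leaving out arrays reduces the sample.

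Whether the replicate numbers pair the arrays is not settled. Deviations from the group means correlated at 0.17, 0.05 and 0.13 for replicates 1, 2 and 3. For replicates 1 and 3 this was above the highest correlation with another number (0.05 and 0.01). Replicate 2 correlated better with another number (0.053 against 0.046). With the replicate block 3 genes were called, the same genes, with 1014 at an unadjusted p under 0.05 against 828, and 8 lists passed; it changed no call among the counts, named genes and lists.

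Directions reversed for these results, none of which had passed. The gut homing mean (-0.05) became 0.037 with pseudocount 64, 0.010 with median scaling, 0.18 with the 60th percentile filter, 0.085 with every probe set, 0.14 without both label-doubt arrays, and -0.33 to 0.10 without single arrays. The macrophage mean (0.06) became -0.020 with pseudocount 64, -0.61 with the 60th percentile filter and -0.25 with every probe set. MHC class II became -0.0019 with every probe set. With specific probe sets only, Cdc20 became -0.17, Hmgcs1 -0.11, Dntt -0.056 and the mitosis mean -0.027. Conventional CD4 became 0.038 with median scaling. Without both label-doubt arrays, Gata3 became -0.0041, Vcam1 -0.39, Th17 0.21, erythroid 0.074 and stroma -0.15. Without both dimmer arrays, Th1 became -0.068, TGF-beta response -0.076, erythroid 0.10 and ribosomal proteins 0.0074. Without single arrays the ranges were -0.34 to 0.10 for Th17, -0.87 to 0.22 for erythroid, -0.31 to 0.060 for DNA replication, -0.10 to 0.073 for conventional CD4, -0.13 to 0.21 for TGF-beta response, -0.17 to 0.36 for mitosis, -0.11 to 0.54 for Foxp3, -0.31 to 0.71 for Dapl1 and -0.091 to 0.80 for Gata3. Of the gene differences under alternatives, 1498 of 1555 kept direction and side of the threshold, 14 newly passed and 33 no longer passed; of the list means, 561 of 687 did, 46 newly passed and 50 no longer passed or, without Nrp1, could not be tested. All 35 array quality values stayed within 1 SD. A group mean within the range of unspiked controls limits the size of the differences of Trav12n-1, Lag3, Entpd1, Scamp1, Atp6v0d2, Prnp, Il10, Oas3, Vcam1, Foxp3, Hspa1a, Lyz2, S100a9 and Dntt.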

Other observations

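The tests of dimmer arrays, of conventional T cells, of the WT replicate 1 label and of receptor segments were chosen after the results were seen; the regroupings of the arrays were planned. T cell receptor segments moved apart in both directions, with a list mean of -0.35 over 8 measured segments (camera adjusted p = 0.779) and, adjusted over the list alone, 3 that rose and 2 that fell. Trav12n-1 had a mean signal of 6.19 in iTreg and 124 in WT Treg, and Trbv13-2 202 and 738 (log2 difference -1.80, adjusted p = 0.110). Trav12n-2 had 2167 and 726 (1.61, adjusted p = 0.131), and Trav9d-3 9479 and 5159 (0.90, adjusted p = 0.470), although another of its probe sets differed by -3.68. Receptor segments are similar in sequence, so the assignment of a probe set to 1 segment is uncertain.

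A restricted receptor repertoire in TBmc cells may contribute to these differences, but the values do not decide it. A single receptor needs 2 segments, 1 alpha and 1 beta. Of 6 alpha and beta segments measured, 4 had a mean iTreg signal above the unspiked controls, against 5 in WT Treg, and of the 4 with specific probe sets 2 did. Probe sets that match several segments, other receptor chains and other differences between the mouse lines stay open, and the transgenic receptor's own segments were not looked up.

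The lower Treg core list may have technical sources. Without the dimmer replicate 3 array of each group the list's mean was -0.94, against -0.92 with them. Each group held 1 dimmer array, so leaving them out could hardly change the difference and is a weak test. The log2 ratio of Gapdh 3′ to 5′ signals, which averaged 2.94 in iTreg and 2.36 in WT Treg, was not tested as a source. That of Actb averaged 0.21 in iTreg and 0.24 in WT Treg. For Gapdh, iTreg replicates 1 and 3 lay above every WT array. Replicate 2 of iTreg, at 2.46, lay below WT replicate 2, at 2.49, while the list's means there were 8.42 and 9.37. Resting conventional T cells in the iTreg sort, which the Foxp3 reporter gate would remove, stay open. Il7r, high in such cells, differed by -1.20 (limma adjusted p = 0.519), a direction against this explanation. Its groups overlapped, and it ranged from -1.57 to -0.75 over the alternatives. The naive or central T cell list was higher, as this explanation would require (camera adjusted p = 0.0448). That call was lost with an estimated correlation (camera adjusted p = 0.533) and held in 10 of 23 alternatives. The iTreg origin, the fed antigen, the receptor and the Nrp gate differ together and stay open, untested.

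The cell type label of WT replicate 1 says Nrp-negative. Its Nrp1 signal lay at a median position of 0.80 between the iTreg mean (0) and the mean of the other WT arrays (1), and on all 4 probe sets above the highest iTreg array by more than 1 SD of the iTreg arrays, which argues against a sort without Nrp1 as far as RNA can show it. Hopx, which was picked because it departs in this array and so tests nothing, had a signal of 955 there, 36.9 and 22.8 in the other WT arrays and 912 in the highest iTreg array. On the 200 genes that best parted the other 5 arrays, on a scale where 1 is the own group and 0 the other, WT replicate 1 lay at 0.52, the lowest of the WT arrays (0.76 and 0.89 for replicates 2 and 3), and iTreg replicate 2 at 0.49, the lowest of the iTreg arrays (0.61 and 0.73 for replicates 1 and 3). By Spearman's rho WT replicate 1 was closest to WT replicate 2 (0.945), followed by iTreg replicate 1 (0.943) and iTreg replicate 2 (0.940), with WT replicate 3 at 0.922; iTreg replicate 1 was closer to it than to any iTreg array. These correlations settle neither label. For WT replicate 1 they point both ways, as it was closest to WT replicate 2 but closer to iTreg replicates 1 and 2 than to WT replicate 3. For iTreg replicate 1, closeness to WT replicate 1 does not mark a wrong label. The array of iTreg replicate 2, whose label is not in doubt, was also closer to WT replicate 1 than to any iTreg array. No biological explanation for this was tested.

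The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. In 1 split, the real one, as many genes were called as the real 3, and the highest other count was 2; the same holds for genes in the commoner direction (3 against 2, 1 split) and for genes changed at least 2-fold (3 against 2, 1 split). As many lists as the real 8 passed in 3 splits, and the highest other count was 13. The real 3 genes include the receptor segment Trav12n-1, and the receptor differs between the groups by design.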
